A study of Schmidtea mediterranea with 35 samples.

How the data were processed

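X1 cells of the CIW4 clonal line of Schmidtea mediterranea, kept at 20 C, were profiled by sequencing of polyA RNA after RNAi by feeding of bacteria with double-stranded RNA against zfp1, p53 or unc22. Per the labels' protocols the animals were fed 3 times at intervals of 3 days, cells were sorted by Hoechst staining, and libraries were made from 100 ng of sorted RNA with the Illumina TruSeq kit. Groups, days and replicate numbers were taken from the labels. The series' design text states that 1 library was discarded for low yield, which leaves 35 libraries in 9 groups. Nothing in the labels says whether replicates came from separate cultures of animals, so p-values measure only the spread between these libraries, which may be technical.

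The authors deposited RPKM values, reads scaled by transcript length and by library, for 25462 transcripts. The submitters' processing notes name CASAVA 1.8.2, Bowtie and edgeR, with no role or order, and the transcript assembly and its version are not given in the sources used here. Whole reads were recovered from the deposited RPKM values with numpy 2.4.6, by finding for each transcript a whole length, and for each library a divisor, that make all values whole multiples of the value of 1 read. All values of 25462 transcripts (100.0%) came out whole within 0.01 reads. On 3930 simulated transcripts the same step recovered 99.69% exactly. The recovered divisors were 0.617 to 1.207 times the total reads of the library, with a geometric mean of 1.0. Total reads ranged from 4391559 to 26115474, and a value of few reads has a wide counting error. No 2 libraries of a group came within sampling noise of each other, since the lowest chi-square per transcript of any pair was 1.8.

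RPKM is not a count, so the test was limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with an intensity trend, a mean for each of the 9 groups and a shared estimate of the spread. Fold changes are on the log2(RPKM + 1) scale, which understates the change of weakly expressed transcripts. Transcripts with at least 1 RPKM in at least 3 libraries were tested, 19206 in all, and called at a Benjamini-Hochberg adjusted p under 0.05. Values in the text are means ± SD over libraries, and log2 fold changes carry the standard error of limma. 12 comparisons were made, namely each knockdown with the control and with the other knockdown on each day, the difference of each knockdown's effect between days 13 and 6, and the control between these days.

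The test was checked on simulated data for 19206 transcripts with 200 changed, all of at least 5 RPKM on average. The median tested transcript was at 3.8 RPKM in the day 6 controls, so the shares recovered do not cover weakly expressed transcripts. Noise was drawn independently for each transcript and library. The shares of false calls therefore leave out deviations common to many transcripts of a library. For p53 RNAi against control at day 13, 28.4% of transcripts changed 1.5-fold, 67.2% of those changed 2-fold and 97.0% of those changed 4-fold were recovered, and 5.9% of calls were false. For zfp1 RNAi against control at day 6 these shares were 26.9%, 71.6% and 95.5%, with 7.2% of calls false. For the difference of the zfp1 effect between days they were 11.9%, 32.8% and 86.4%.

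The file pairs no identifier with a gene name and no annotation was used here. Gene lists of neoblast classes, epidermal progeny, other planarian cell types and cell processes had been fixed before the data were examined. They could not be applied, and neither could the check of both target genes or the markers of other cell types. The rule fixed for named transcripts took, for each comparison with the control, the 2 largest rises and the 2 largest falls among called transcripts whose libraries did not overlap between the groups. For shared calls, unchanged groups were simulated 50 times against the controls, with the spread pooled over all groups and, added after that result was seen, with the spread of each day's controls. Alternatives fixed before the data were examined were other pseudocounts (0.1 and 5 RPKM), other filters, median-ratio and quantile scaling, robust empirical Bayes, fits on the compared groups alone, replicate blocks, a log2 fold minimum of 1, leaving out each library in turn, and split controls. Those added after seeing the data were limma-voom on the recovered reads without and with library quality weights, cyclic loess scaling, reads thinned to the lowest total, and leaving out the 3 libraries with the most transcripts at 0. Replicate numbers recur between groups. In 1 of 9 comparisons, zfp1 RNAi against control at day 13, every pair of libraries with the same number deviated together from the group means, with correlations of 0.52, 0.18 and 0.58. This pairing comes from the values alone, since the labels give the numbers no meaning. For the difference between days, residuals of a model with equal effects on both days were regrouped between days within each RNAi, in 100 groupings with the real one, a test chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.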

Results

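Neoblasts, the dividing stem cells of the planarian flatworm Schmidtea mediterranea, were profiled after RNAi knockdown of zfp1 or p53. The series title states its purpose as finding factors of neoblast differentiation. In planarians zfp-1 is known as a zinc finger gene of neoblasts fated to the epidermis, and p53 is the homolog of the vertebrate tumour suppressor. The control was RNAi against unc22, which the labels call non-targeting. X1 cells, a sorting gate of Hoechst-stained cells that holds cycling neoblasts, were collected at days 6, 9 and 13 of treatment. Each of the 9 groups of RNAi and day held 4 libraries, except the unc22 group at day 13, which held 3. The deposited table gave RPKM for 25462 transcripts in 35 libraries. Whole reads recovered from these values summed to between 4391559 and 26115474 reads per library, with a median of 11272890. By group, the shallowest library had 4.39 M reads after zfp1 RNAi at day 6, 4.45 M after p53 RNAi at day 13 and 7.47 M in the unc22 control at day 9.

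The transcripts carry only assembly identifiers that the file does not pair with gene names. The levels of zfp1 and p53 could therefore not be used to check the knockdowns, and transcripts are grouped below by how they changed, not by pathway or cell type. Of the 25462 transcripts, 19206 passed the filter on low values and were tested with limma.

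3 libraries stood apart from the others in their group, namely zfp1 RNAi day 6 replicate 1, zfp1 RNAi day 13 replicate 5 and unc22 day 13 replicate 5. They had 4945, 5021 and 4546 transcripts at 0. The most abundant transcript took 25.2%, 32.3% and 27.5% of their reads. The most transcripts at 0 in any other library was 3588, in zfp1 RNAi day 6 replicate 4, the shallowest library.

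**Figure D1:**
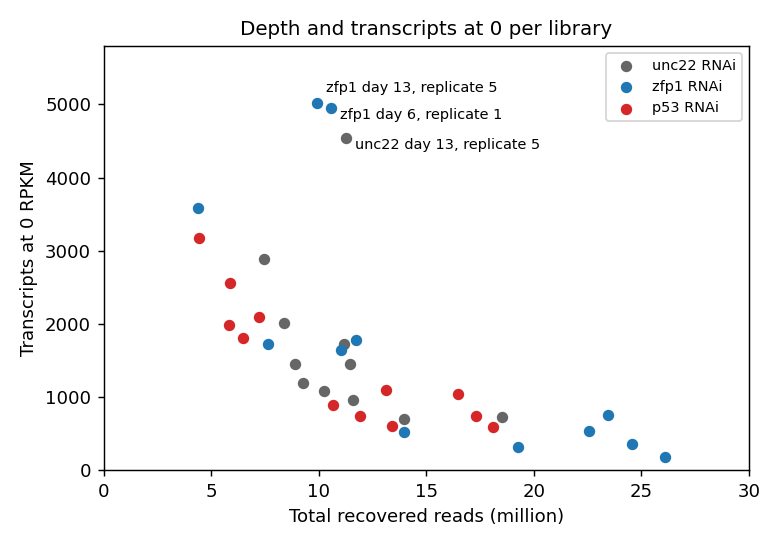
Transcripts listed at 0 RPKM (y axis) against total recovered reads in M (x axis) for the 35 libraries, coloured by RNAi target. The labelled libraries have 4945, 5021 and 4546 transcripts at 0 with 10.6, 9.92 and 11.3 M reads, above all other libraries.

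The comparison of zfp1 RNAi with the control asked which neoblast transcripts change when zfp1 is knocked down. At day 6, in limma with Benjamini-Hochberg adjustment, 169 transcripts were lower and 81 higher. SMED30012332 fell from 31.5 ± 2.77 RPKM (SD, n = 4) in the control to 2.92 ± 1.11 RPKM (SD, n = 4), a log2 fold change of -3.10 ± 0.17 (SE; adjusted p = 1.0e-13, limma). SMED30011490 fell from 21.8 ± 2.05 to 1.58 ± 0.688 RPKM, a log2 fold change of -3.19 ± 0.23 (SE). The largest rises were those of SMED30002500, from 3.32 ± 0.537 to 19.4 ± 7.18 RPKM, and SMED30028059, from 4.39 ± 0.997 to 14.9 ± 4.18 RPKM. Their log2 fold changes were 2.19 ± 0.18 and 1.54 ± 0.23 (SE). Without the 3 libraries that stood apart, an alternative chosen after seeing the data, 229 transcripts were higher and 335 lower at day 6, 564 in place of 250. With a fit on the libraries of these groups alone 5 were higher and 40 lower. The balance turned with library quality weights, also chosen after seeing the data, to 255 higher and 230 lower.

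At day 9, 415 transcripts were higher and 206 lower after zfp1 RNAi. SMED30012332 was at 1.36 ± 0.132 RPKM against 39.6 ± 4.48 RPKM in the control (log2 fold change -4.10 ± 0.17, SE). SMED30023708, an abundant transcript at 148 ± 30.8 RPKM in the control, was at 7.71 ± 3.8 RPKM (-4.19 ± 0.26, SE). SMED30035446 rose from 1.08 ± 0.664 to 8.1 ± 2.08 RPKM and SMED30034731 from 8.99 ± 3.9 to 39.5 ± 5.3 RPKM. Without the 3 libraries that stood apart, none of which is from day 9, the count was 970 in place of 621. The log2 fold changes are the same there, so the count moved through the shared estimate of the spread.

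At day 13, 443 transcripts were higher and 408 lower after zfp1 RNAi. SMED30012332 was at 0.539 ± 0.0837 RPKM (SD, n = 4) against 38.7 ± 1.5 RPKM (SD, n = 3), a log2 fold change of -4.69 ± 0.19 (SE). SMED30011490 was at 0.304 ± 0.178 against 30.2 ± 13 RPKM (-4.51 ± 0.25, SE). The largest rises were those of SMED30025751 (5.3 ± 0.992 to 35.9 ± 9.12 RPKM; log2 fold change 2.53 ± 0.36, SE) and SMED30012371 (14.7 ± 3.55 to 79 ± 15.1 RPKM; 2.35 ± 0.25, SE). In the control itself SMED30012371 fell by 1.70 ± 0.25 (SE) on the log2 scale between days 6 and 13. This comparison holds 2 of the libraries that stood apart, replicate 5 of each group, and its count of 851 became 190 in a fit on these groups alone and 902 without the 3 libraries. The balance turned to 71 higher and 119 lower in the fit on these groups alone, 382 and 451 with a pseudocount of 5 RPKM, and 1482 and 1776 with library quality weights.

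**Figure D2:**
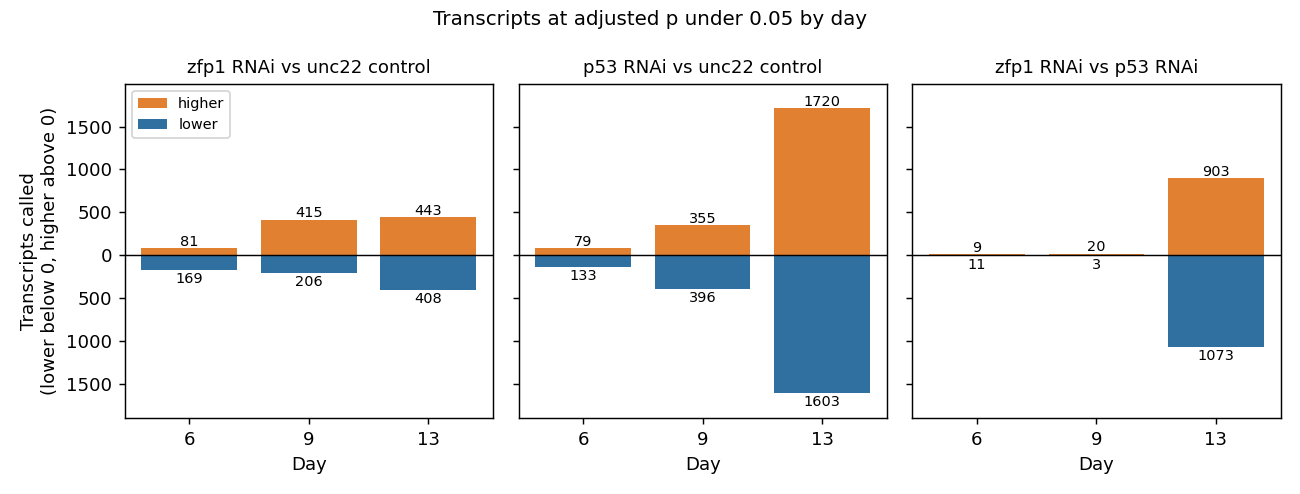
Number of transcripts called (adjusted p under 0.05, limma) at days 6, 9 and 13, higher above 0 and lower below 0, for zfp1 RNAi against control, p53 RNAi against control, and zfp1 RNAi against p53 RNAi. The counts for p53 RNAi at day 13, 1720 higher and 1603 lower, are the largest of the 9 comparisons.

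The same comparison for p53 RNAi gave 133 lower and 79 higher transcripts at day 6. SMED30011419 was at 0.348 ± 0.13 RPKM against 23.8 ± 5.56 RPKM in the control, a log2 fold change of -4.18 ± 0.32 (SE; adjusted p = 6.9e-11, limma). SMED30023874 was at 3.78 ± 0.494 against 62.8 ± 3.83 RPKM (-3.74 ± 0.20, SE). The leading rises were smaller. SMED30008464 went from 1.82 ± 0.156 to 5.98 ± 0.725 RPKM and SMED30005036 from 1.04 ± 0.225 to 3.86 ± 0.593 RPKM, with log2 fold changes of 1.30 ± 0.21 and 1.25 ± 0.18 (SE). Without the 3 libraries that stood apart, 218 transcripts were higher and 199 lower.

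At day 9, p53 RNAi gave 396 lower and 355 higher transcripts. SMED30012332 was at 0.694 ± 0.283 RPKM (log2 fold change -4.59 ± 0.17, SE) and SMED30023874 at 2.53 ± 0.696 RPKM (-4.37 ± 0.20, SE), against 39.6 ± 4.48 and 72.1 ± 17.7 RPKM in the control. The leading rises were of short, weakly expressed transcripts, SMED30021636 (0.313 ± 0.244 to 5.04 ± 5.48 RPKM) and SMED30002689 (1.26 ± 1.21 to 6.06 ± 1.55 RPKM). Their calls ended in 9 and 6 of 22 alternatives, both of them when p53 day 9 replicate 4 was left out. The log2 fold change of SMED30021636 went from 1.81 ± 0.49 to 1.27 ± 0.47 (SE; adjusted p = 2.0e-01, limma). That of SMED30002689 stayed about as large, 1.75 ± 0.44 and then 1.67 ± 0.48 (SE; adjusted p = 5.6e-02, limma). The calls also ended with limma-voom on the recovered reads, where the log2 fold changes were 3.24 ± 0.99 and 2.32 ± 0.69 (SE). Without the 3 libraries that stood apart the count at day 9 was 1811 in place of 751, again through the shared estimate of the spread.

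At day 13, 3323 transcripts were called after p53 RNAi, 1720 higher and 1603 lower. SMED30026364 was at 2.16 ± 0.515 RPKM (SD, n = 4) against 89.6 ± 18.9 RPKM (SD, n = 3), a log2 fold change of -4.84 ± 0.20 (SE; adjusted p = 1.7e-17, limma). SMED30023708 was at 7.04 ± 0.675 against 197 ± 30.2 RPKM (-4.62 ± 0.28, SE). SMED30030712 rose from 4.77 ± 0.323 to 48 ± 4.72 RPKM (3.08 ± 0.23, SE). It was not called after p53 RNAi at day 6 (-0.21 ± 0.21, SE) or day 9 (0.15 ± 0.21, SE), nor after zfp1 RNAi at day 13 (0.21 ± 0.23, SE), and the difference between the knockdowns at day 13 was itself called (-2.87 ± 0.21, SE; adjusted p = 3.6e-11, limma). The other leading rise, of SMED30005552 (16.4 ± 14.3 to 84 ± 44.8 RPKM), depended in part on unc22 day 13 replicate 5, where it was listed at 0. Without that library its log2 fold change was 1.56 ± 1.06 (SE; adjusted p = 5.0e-01, limma) in place of 3.12 ± 1.06.

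In the day 9 controls, which are not in this comparison, the transcripts lower after p53 RNAi at day 13 had a median of 27.3 RPKM, the higher ones 1.38 RPKM and all tested transcripts 3.68 RPKM. With calls made without unc22 day 13 replicate 5, 570 lower and 1021 higher, the medians were 11.3 and 1.31 RPKM, so part of the contrast in abundance depended on that library. In the other comparisons with the control, the lower transcripts also had the higher median in the controls of the same day. For zfp1 RNAi at day 13 these medians were 8.28 and 1.66 RPKM. On the log2(RPKM + 1) scale a transcript near 1 RPKM has little room to fall. The near-even balance depended on the filter, the threshold and the scaling. It was 397 higher and 1322 lower among transcripts of at least 5 RPKM on average, 698 and 341 at a log2 fold change of at least 1, and 1370 and 1037 after cyclic loess scaling. Most of these calls were not made earlier. 1308 of the lower and 1439 of the higher transcripts were called at day 13 and at neither earlier day, against 230 and 190 after zfp1 RNAi. A call at day 13 alone is not a test of a difference between days. The test of the p53 effect between days 13 and 6 called 376 transcripts. At day 9, 1324 of the 1603 lower transcripts had a negative log2 fold change, and 1402 of the 1720 higher ones a positive one. Leaving out unc22 day 13 replicate 5 reduced the count from 3323 to 1591. With all of the 3 libraries that stood apart left out it was 2749.

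**Figure D3:**
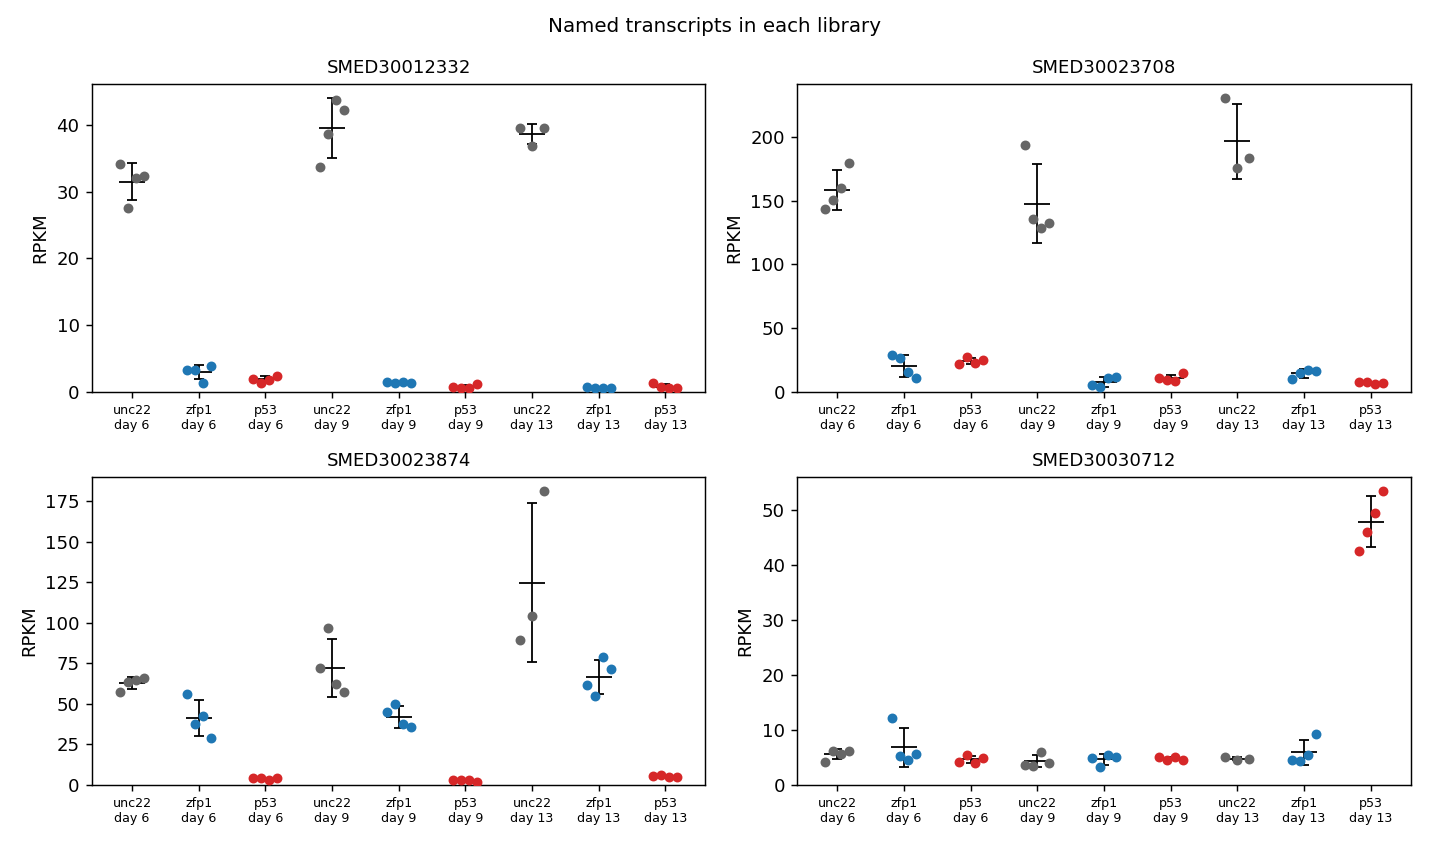
RPKM (y axis) of 4 named transcripts in each library, by RNAi target and day; points are libraries and bars the mean and SD (n = 4, or n = 3 for unc22 at day 13). SMED30012332 and SMED30023708 are low in both knockdowns on every day, SMED30023874 is at 2.53 to 5.24 RPKM on average after p53 RNAi and at 41.2 to 66.7 RPKM after zfp1 RNAi, and SMED30030712 is at 48 RPKM after p53 RNAi at day 13 and below 7 RPKM on average in the other groups.

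Calls were shared between the knockdowns. At day 6, 101 transcripts were lower and 40 higher in both, with none in opposite directions. In fits on the compared groups alone 36 were lower and 4 higher, and with library quality weights the balance turned to 193 higher and 179 lower. At day 9 the shared calls were 174 lower and 244 higher, and at day 13 they were 310 lower and 330 higher, with 10 in opposite directions. Fits on the compared groups alone gave 181 shared calls at day 13 in place of 640. Independent lists of these sizes would share 1.17 and 0.333 transcripts at day 6, 4.25 and 7.67 at day 9, and 34.1 and 39.7 at day 13. Both knockdowns were compared with the same control libraries. In 50 simulations of unchanged groups against these controls the number of shared calls was at most 1 on any day. Each transcript and library was drawn independently there. The simulations therefore do not show how many calls would be shared through deviations common to many transcripts of a library. With the controls split so that each knockdown had its own 2 libraries, 57 to 72 transcripts were shared at day 6 and 196 to 208 at day 9 over the 6 assignments. With 3 controls no such split could be made at day 13, where part of the excess may come from the shared controls.

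Across transcripts, which are not independent replicates, the log2 fold changes of the knockdowns correlated at 0.42, 0.63 and 0.60 at days 6, 9 and 13. The simulated correlations with no effect, from the same independent draws, were 0.50, 0.50 and 0.57. The covariances were 0.0367, 0.0715 and 0.134. Unchanged groups gave 0.017, 0.0247 and 0.0601 with the spread of each day's controls, leaving differences of 0.0197, 0.0468 and 0.0739. With the spread pooled over all groups they gave 0.0336, 0.0337 and 0.0447, and the difference at day 6 was then 0.00307.

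Lists were also carried to comparisons of groups that share no library with the list's own. The estimate of the spread is still shared, so the calls, though not the log2 fold changes, draw on libraries in common. Of the 169 transcripts lower after zfp1 RNAi at day 6, 169 had a negative log2 fold change after p53 RNAi at day 9 and 143 were called lower there, against 3.48 for independent lists. Their median log2 fold change there was -1.05. Of the 133 transcripts lower after p53 RNAi at day 6, 132 had a negative log2 fold change after zfp1 RNAi at day 9 and 117 were called, with a median of -1.16. Of the 81 transcripts higher after zfp1 RNAi at day 6, 59 were called higher after p53 RNAi at day 9.

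86 transcripts were called lower and 30 higher in all 6 comparisons with the control. In fits on the compared groups alone the sets were 32 and 0 (limma), and leaving out 1 library took the higher set to as few as 14. The median transcript of the lower set was at 5.53 ± 0.198 RPKM (SD over library medians, n = 4) in the day 6 control, at 1.14 ± 0.236 RPKM after zfp1 RNAi and at 1.04 ± 0.177 RPKM after p53 RNAi. At day 13 the same medians were 7.08 ± 0.982 (n = 3), 0.559 ± 0.073 and 0.629 ± 0.0846 RPKM. For the higher set they were 5.37 ± 0.783, 10.6 ± 0.826 and 9.68 ± 0.88 RPKM at day 6. These sets were chosen on the libraries in which their levels are given.

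**Figure D4:**
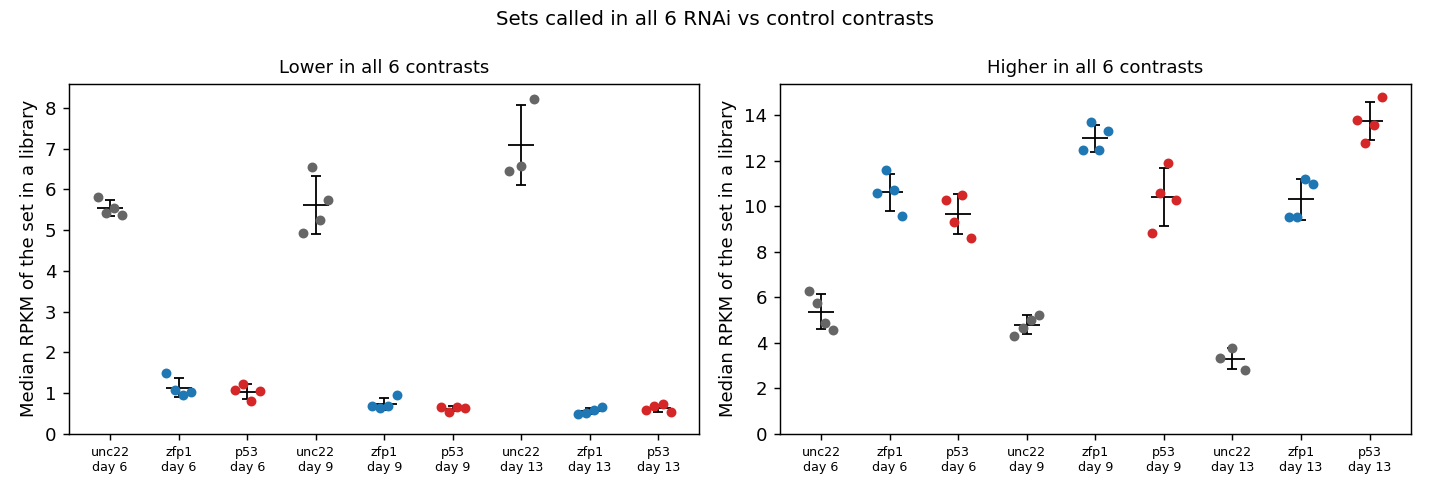
Median RPKM (y axis) of the 86 transcripts called lower (left) and the 30 called higher (right) in all 6 comparisons, in each library by RNAi target and day; bars are the mean and SD over libraries (n = 4, or n = 3 for unc22 at day 13). The lower set averages 5.53 to 7.08 RPKM in the controls and at most 1.14 RPKM in the knockdown groups.

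The direct comparison of zfp1 with p53 RNAi used no control library for its log2 differences. Its SE and calls used the estimate of the spread shared by all groups, the controls included. It called 20 transcripts at day 6 (9 higher after zfp1 RNAi), 23 at day 9 (20 higher) and 1976 at day 13 (903 higher). These counts moved far between settings. At day 9, 167 were higher and 63 lower without the 3 libraries that stood apart, 596 and 478 with library quality weights, 44 and 12 with quantile scaling, and as few as 9 in all with 1 library left out. At day 6 the count was 55 without the 3 libraries. SMED30023874 had a log2 difference of 3.11 ± 0.20 (SE) between zfp1 and p53 RNAi at day 6, 3.62 ± 0.20 at day 9 and 3.43 ± 0.20 at day 13. Against the control it changed after zfp1 RNAi by -0.63 ± 0.20 at day 6, which was not called, -0.75 ± 0.20 at day 9 and -0.84 ± 0.21 at day 13 (SE). The latter 2 calls ended in 5 and 4 alternatives, among them at day 13 the removal of unc22 day 13 replicate 5 (-0.54 ± 0.22, SE). 5 transcripts differed the same way on all 3 days, each lower after p53 than after zfp1 RNAi. They were SMED30023874, SMED30026364, SMED30023071, SMED30035864 and SMED30017565, and the last 3 were chosen after their values were seen. SMED30035864 was at 33.9 ± 1.16 RPKM after zfp1 RNAi, 9.6 ± 1.2 RPKM after p53 RNAi and 21.5 ± 2.49 RPKM in the control at day 13, so that it was called higher in the former (0.64 ± 0.11, SE) and lower in the latter (-1.09 ± 0.11, SE). The rise was not called in the fit on the compared groups alone (0.64 ± 0.19, SE; adjusted p = 2.5e-01, limma). In a fit on the compared groups alone only 1 transcript was called at day 6, and the day 6 calls of 4 of the 5 ended. The log2 differences are the same there, while the SE rose from 0.18 to 0.27 for SMED30026364, from 0.19 to 0.24 for SMED30023071, from 0.11 to 0.16 for SMED30035864 and from 0.18 to 0.27 for SMED30017565. The adjusted p was 4.7e-01, 9.2e-01, 6.6e-01 and 9.2e-01. The zfp1 group at day 6 holds replicate 1, which stood apart. The call of SMED30017565 at day 6 (0.86 ± 0.18, SE) also ended when p53 day 6 replicate 3 was left out (adjusted p = 2.1e-01, limma), with a log2 difference of 0.77 ± 0.19 (SE). Its calls at days 6 and 13 ended in 11 and 4 of 22 alternatives. SMED30011419 differed at day 6 by 2.66 ± 0.32 (SE) and was not called at day 9 (0.54 ± 0.32) or day 13 (0.05 ± 0.32). In zfp1 RNAi day 6 replicate 1, which stood apart, it was at 24.4 RPKM against 4.73 to 5.03 RPKM in the other 3 libraries. The log2 difference was 2.13 ± 0.23 (SE), still called, without that library, and 2.66 ± 0.45 (SE; adjusted p = 5.3e-01, limma), not called, in the fit on the compared groups alone. The balance at day 13 turned to 793 higher and 228 lower among transcripts of at least 5 RPKM on average, and to 850 and 723 with a pseudocount of 0.1 RPKM. At day 13 the count was 875 without zfp1 day 13 replicate 5 and 3080 without zfp1 day 13 replicate 2.

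The effect of zfp1 RNAi differed between days 6 and 13 for 46 transcripts and that of p53 RNAi for 376, of which 275 were higher and 101 lower at day 13. The balance for p53 RNAi was even in other settings, with 54 higher and 51 lower among transcripts of at least 5 RPKM on average and 1012 and 1004 with library quality weights. The zfp1 count is uncertain. In a fit on the compared groups alone limma called 0 transcripts, with 766 at an unadjusted p under 0.05. That is fewer than 0.05 of the 19206 tested, the share that chance alone would give. Of 100 splits of the libraries within days, the real one included, 18 gave at least 46. The zfp1 differences named here were not called in that fit, with adjusted p of 1.6e-01 for SMED30012332 and 7.4e-02 for SMED30002500. Their log2 differences are the same there, and the SE is 0.30 in place of 0.26 and 0.34 in place of 0.27. SMED30012332 fell further by day 13 than at day 6 after zfp1 RNAi, by 1.59 ± 0.26 (SE) on the log2 scale, and after p53 RNAi, by 0.99 ± 0.26, a call that ended in 16 of 30 alternatives with log2 differences of -0.76 to -1.01. SMED30002500 rose at day 6 after zfp1 RNAi and its effect at day 13 was lower by a log2 difference of -2.39 ± 0.27 (SE). SMED30030712 had the opposite course after p53 RNAi, with a difference of 3.30 ± 0.31 (SE). In the control itself 329 transcripts differed between days 13 and 6, 214 higher and 115 lower. The balance was nearer even with a pseudocount of 0.1 RPKM, 177 and 161, and in a fit on these groups alone, 30 and 25. Day and harvest cannot be separated in that comparison, and without unc22 day 13 replicate 5 the count was 81. The p53 count was 194 without the same library.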

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

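The tests on split libraries, cyclic loess scaling, thinned reads, split controls and predicted reads were written down before their results were seen. The tests on depth, on zfp1 RNAi and on the replicate 5 libraries, and the splits that part pairs and the regrouping between days, were chosen after the values were seen.

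In groups of 4 libraries, 71 values were tested for a library far from the others, and 10 passed the limit for the gap over the range, where chance gives about 3.55. zfp1 day 13 replicate 5 had 9.92 M reads against 22.6 to 24.5 M in its group, and 5021 transcripts at 0 against 365 to 761. zfp1 day 6 replicate 1 had an RPKM divisor of 0.812 times its reads against 1.09 to 1.13. p53 day 13 replicate 1 had 3168 transcripts at 0 against 589 to 747. The most abundant transcript took 19.8% of reads in p53 day 6 replicate 4 against 12.9% to 13.7%, and unc22 day 6 replicate 3 had 13.9 M reads against 8.39 to 9.25 M. Among named transcripts, SMED30011490 was at 24.9 RPKM in unc22 day 6 replicate 4 against 20.6 to 21.1 RPKM. SMED30023708 was at 194 RPKM in unc22 day 9 replicate 1 against 129 to 136 RPKM. SMED30023874 was at 3.04 RPKM in p53 day 6 replicate 3 against 3.99 to 4.09 RPKM, and SMED30002689 at 3.75 RPKM in p53 day 9 replicate 2 against 6.64 to 7.03 RPKM.

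The libraries that stood apart, zfp1 day 6 replicate 1, zfp1 day 13 replicate 5 and unc22 day 13 replicate 5, had at least 4546 transcripts at 0, and their deviations from their group correlated at 0.46 to 0.58 across transcripts. Lower depth alone would not give this, since the most transcripts at 0 in any of the 11 libraries with fewer reads was 3588. zfp1 RNAi alone would not either, because 1 of the 3 is a control library. Some transcripts had at least 10 reads predicted from the rest of the group but none observed. They numbered 47 to 576 in these libraries and at most 22 in the other 32. This excess was predicted for fewer distinct molecules in the library. It was also favoured by the choice of these libraries for their transcripts at 0, so it does not single out that cause. RNA quality and a shared preparation stay open, as the labels give no batch.

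The 2 knockdowns differed directly in 20 transcripts at day 6, 23 at day 9 and 1976 at day 13. All of these counts depend on the processing. Days 6 and 9 gave 55 and 230 without the 3 libraries, and day 9 gave 1074 with library quality weights. A fit on the compared groups alone gave 1, 12 and 555 at days 6, 9 and 13.

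At day 13 p53 RNAi gave 3.9 times as many calls as zfp1 RNAi. The ratio was 2.61 after cyclic loess scaling and 4 with reads thinned to the lowest total. This argues against a trend with expression or unequal depth as the whole cause. Depth ranged higher after zfp1 RNAi, 9.92 to 24.5 M reads against 4.45 to 18.1 M after p53 RNAi. Without both replicate 5 libraries the ratio was 3.39, but zfp1 RNAi then has fewer libraries than p53 RNAi. The part of those libraries is therefore not decided by it. Without unc22 day 13 replicate 5 alone the ratio was 2.32, and with library quality weights 1.77. With the replicate number within day as a block it was 1.45, below the bound of 1.5 set for the other tests, while a fit on the compared groups alone gave 12.2 and a filter at 5 RPKM 4.49, so the size of the excess depends on the fit. A stronger or later effect of p53 RNAi on these cells remains a hypothesis, and an unequal strength of knockdown, which could not be measured, may give the same pattern.

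Transcripts called in the same direction in both knockdowns far outnumbered those of independent lists. Shared control libraries alone would bring the covariance of the log2 fold changes to 0 on average once each knockdown has its own controls. The lowest covariance over the 12 assignments at days 6 and 9 was 0.012. The assignments of a day reuse the same libraries, and no spread of this covariance without an effect was computed. A part from deviations common to libraries of different groups is therefore not excluded. Loss of a common group of cells or a common program from the X1 gate is a candidate explanation that was not tested, because no markers could be named. At day 13 the controls could not be split.

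The effect of zfp1 RNAi differed between days 13 and 6 for 46 transcripts and that of p53 RNAi for 376, by the test of the difference itself. Among named transcripts the log2 difference for zfp1 RNAi was -2.39 for SMED30002500, -1.59 for SMED30012332, 2.15 for SMED30012371 and -2.47 for SMED30011419. None of these 4 was called in the fit on the compared groups alone, where the log2 differences are the same and the adjusted p was 7.4e-02, 1.6e-01, 1.2e-01 and 4.7e-01. For p53 RNAi it was -1.07 for SMED30002500, -1.72 for SMED30011490, -0.99 for SMED30012332 and -1.96 for SMED30023708. It was 2.41 for SMED30012371, 3.30 for SMED30030712 and -1.44 for SMED30026364, and these 7 stayed called in that fit, though SMED30012332 lost the call in 16 of 30 alternatives and SMED30002500 in 11.

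Each count was set against other splits of the same libraries. For zfp1 RNAi against control, only the real one of 35 splits gave as many calls at day 6, 250 against at most 11. The same held at day 9, with 621 against at most 0. A share of 1 in 35 is the lowest that these splits can give, so they argue against chance without excluding it. At day 13, 4 of 35 splits gave at least 851 calls and the highest other split gave 4109, so chance cannot be excluded for the count by these splits. The split with 4109 calls set zfp1 replicates 1 and 2 with unc22 replicates 1 and 4 apart from zfp1 replicates 4 and 5 and unc22 replicate 5, which points to a structure of the samples that keeps both replicate 5 libraries together. Libraries of the same replicate number deviated together here, and that split keeps 2 of the 3 pairs, replicates 1 and 5, together. A pairing by number is not established. The deviations of unc22 day 13 replicate 5 correlated at 0.58 with zfp1 day 13 replicate 5, but also at 0.55 with zfp1 day 6 replicate 1. Of the 8 splits that part all 3 pairs, too few for a share under 0.05, the real one gave the most calls, 851 against at most 199, or 1271 against at most 527 with the number as a block. The transcripts called at day 9, from other libraries, moved the same way at day 13 in 206 of 206 falls and 404 of 415 rises.

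For p53 RNAi only the real split gave as many calls on each day, with 212 against at most 0, 751 against at most 0 and 3323 against at most 1194. For zfp1 against p53 RNAi the real counts of 20, 23 and 1976 stood against at most 12, 0 and 7. For the control between days 329 stood against at most 3. Each of these 7 counts was the highest of its 35 splits, the lowest share possible, which argues against chance without excluding it. The day 6 count of zfp1 against p53 RNAi is the weakest of them. It was 20 against 12 in another split, and 1 in a fit on the compared groups alone, where the other splits were not run. For the difference between days, 3 of 100 drawn splits within days gave at least 376 calls for p53 RNAi, with 854 the highest other, and 18 of 100 gave at least 46 for zfp1 RNAi, with 3476 the highest other. These splits mix the effect on each day and do not make it equal on both. Libraries were therefore also regrouped between days, as residuals of a model with equal effects. For p53 RNAi only the real one of 100 such groupings gave at least 376 calls, with 1 the highest other. This argues against chance there. For zfp1 RNAi 4 gave at least 46, with 1241 the highest other. The 2 tests part for zfp1 RNAi, so chance is not taken as excluded, and the high counts point to a structure of the libraries apart from their groups.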

How the results depend on the processing

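The results for limma-voom, library quality weights, cyclic loess scaling, thinned reads and the removal of 3 libraries were chosen after seeing the data. Pseudocounts of 0.1 and 5 RPKM, no filter on low values, median-ratio scaling and robust empirical Bayes left each count within 1.5 times the value reported. The values below lie outside it. Except where stated, the causes were not tested. Tests of gene lists were not run, since no names were paired, nor were the planned count tests, since the deposited unit is RPKM. Depth limits the weakly expressed transcripts, and counts fell when reads were thinned.

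All 108 called effects of the named transcripts were followed, those between days included. They kept their sign in all 2516 alternative values, and 165 lost the call, in 33 effects of 19 transcripts. Of these losses 82 came with 1 library left out and 22 in the fit on the compared groups alone, where the log2 fold changes are the same. 10 effects lost the call only in that fit. The most losses were those of SMED30012332 for the p53 difference between days, 16 of 30, and SMED30008464 for zfp1 against p53 RNAi at day 13, 14 of 22. SMED30005552 at day 13 gave 1.56 without unc22 day 13 replicate 5.

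With only transcripts of at least 5 RPKM on average, and so fewer transcripts tested, the count was, for zfp1 RNAi against control 107, 241 and 383 at days 6, 9 and 13, and for p53 RNAi against control 94, 330 and 1719 at days 6, 9 and 13. Between zfp1 and p53 RNAi the comparison gave 13 and 1021 at days 6 and 13, and the calls shared by both knockdowns came to 64, 170 and 283 at days 6, 9 and 13. Between days the zfp1 difference gave 28, and the p53 difference between days gave 105. The set lower in all 6 comparisons gave 30. With a log2 fold change of at least 1, the count was, for zfp1 RNAi against control 117, 254 and 358 at days 6, 9 and 13, and for p53 RNAi against control 97, 254 and 1039 at days 6, 9 and 13. The comparison of zfp1 with p53 RNAi gave 9, 13 and 351 at days 6, 9 and 13, and the calls shared by both knockdowns came to 62, 157 and 287 at days 6, 9 and 13. The p53 difference between days gave 248, and the control between days gave 105. The set lower in all 6 comparisons gave 46, and the set higher in all 6 comparisons gave 5.

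With a fit on the compared groups alone the count was, for zfp1 RNAi against control 45 and 190 at days 6 and 13, and for p53 RNAi against control 444 at day 9. The comparison of zfp1 with p53 RNAi gave 1, 12 and 555 at days 6, 9 and 13, and the calls shared by both knockdowns came to 40 and 181 at days 6 and 13. The zfp1 difference between days gave 0, and the control between days gave 55. The set lower in all 6 comparisons gave 32, and the set higher in all 6 comparisons gave 0. In that fit limma called 0 transcripts for the zfp1 difference between days, with 766 at an unadjusted p under 0.05. Chance alone would give a share of 0.05 of the 19206 tested, which is more than 766.

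With quantile normalization the count was, for zfp1 against p53 RNAi 56 and 1271 at days 9 and 13. With cyclic loess scaling the count was, for zfp1 against p53 RNAi 38 and 1108 at days 9 and 13. Cyclic loess scaling moved the zfp1 against p53 calls from 9 higher and 11 lower to 9 and 6 at day 6, and from 20 and 3 to 26 and 12 at day 9. With limma-voom on recovered reads the count was, for zfp1 against p53 RNAi 11 at day 6.

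With library quality weights the count was, for zfp1 RNAi against control 485, 1908 and 3258 at days 6, 9 and 13, and for p53 RNAi against control 956, 2142 and 5770 at days 6, 9 and 13. The comparison of zfp1 with p53 RNAi gave 1074 and 4518 at days 9 and 13, and the calls shared by both knockdowns came to 372, 949 and 2046 at days 6, 9 and 13. The zfp1 difference between days gave 348, and the p53 difference between days gave 2016. The control between days gave 2788, and the set lower in all 6 comparisons gave 154. The set higher in all 6 comparisons gave 139.

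Without the 3 libraries that stood apart the count was, for zfp1 RNAi against control 564 and 970 at days 6 and 9, and for p53 RNAi against control 417 and 1811 at days 6 and 9. The comparison of zfp1 with p53 RNAi gave 55 and 230 at days 6 and 9, and the calls shared by both knockdowns came to 260 and 709 at days 6 and 9. The zfp1 difference between days gave 104, and the set higher in all 6 comparisons gave 73. None of the 3 libraries is in the day 9 comparisons or in p53 RNAi against control at day 6. The log2 fold changes there are the same, so those counts moved through the shared estimate of the spread. With reads thinned to the lowest total, and so fewer reads, the count was, for zfp1 RNAi against control 147 and 412 at days 6 and 9, and for p53 RNAi against control 126 and 448 at days 6 and 9. Direct comparison of zfp1 with p53 RNAi gave 11 and 1152 at days 6 and 13, and the calls shared by both knockdowns came to 76 and 253 at days 6 and 9. The zfp1 difference between days gave 21, and the p53 difference between days gave 144. The control between days gave 187, and the set lower in all 6 comparisons gave 54. The set higher in all 6 comparisons gave 12. With split controls, and so fewer libraries, the count was, for the calls shared by both knockdowns 64.5 and 203.5 at days 6 and 9. With split controls the mean covariance of the log2 fold changes was 0.0199 at day 6 and 0.0475 at day 9.

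Replicate numbers are shared between groups. Of 32 pairs with the same number and day, 16 correlated above 0.1 in their deviations from the group means, over a range of -0.39 to 0.61, and 15 correlated best with their own number. Every pair passed 0.1 in 1 of 9 comparisons, zfp1 RNAi against control at day 13, where the block gave 1271 calls in place of 851. In the other comparisons the numbers were not taken to pair the samples, and p53 RNAi and control at day 13 share only 2 numbers. With the replicate number within day as a block the count was, for p53 RNAi against control 1133 and 1841 at days 9 and 13, and for zfp1 against p53 RNAi 35, 66 and 914 at days 6, 9 and 13. The zfp1 difference between days gave 117, and the control between days gave 33, 16 higher and 17 lower. The set higher in all 6 comparisons gave 47. The block moved no other count by over 1.5 times, and the p53 count at day 13 was then 1.45 times the zfp1 count. With the number across days as a block the count was, for zfp1 against p53 RNAi 35, 79 and 1139 at days 6, 9 and 13, and for the zfp1 difference between days 82.

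Leaving out each library in turn kept the counts not named here within 1.5 times. It gave 1591 to 3413 calls for p53 RNAi at day 13, the lowest without unc22 day 13 replicate 5. The zfp1 against p53 count ranged from 9 to 27 at day 6, with 9 without p53 replicate 1, 13 without p53 replicate 3 or 4 and 10 without zfp1 replicate 4. At day 9 it ranged from 9 to 19, with 13 without p53 replicate 4 and 9, 12 and 15 without zfp1 replicates 1, 2 and 4. At day 13 it ranged from 875 to 3080, with 1296, 1039 and 1011 without p53 replicates 1, 2 and 3, and 3080 and 875 without zfp1 replicates 2 and 5. For the zfp1 difference between days the range was 29 to 71, with 71 without zfp1 day 6 replicate 2, 30 and 29 without zfp1 day 13 replicates 1 and 2, and 30 without unc22 day 6 replicate 1. The p53 difference ranged from 194 to 452, with 248 without p53 day 13 replicate 3 and 194 without unc22 day 13 replicate 5. The control between days ranged from 81 to 405, with 173, 153 and 166 without unc22 day 6 replicates 1, 2 and 3 and 81 without day 13 replicate 5. The set higher in all 6 comparisons ranged from 14 to 36, with 18 without p53 day 6 replicate 1 and 16, 14 and 14 without unc22 day 6 replicates 2, 3 and 4.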

Other observations

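Falls after zfp1 RNAi persisted. Of the 206 transcripts lower at day 9, 206 had a negative log2 fold change at day 13 and 167 were called lower there, against 4.38 for independent lists. Their median log2 fold change at day 13 was -1.18. The compared groups have no library in common, but the estimate of the spread is shared. Of the transcripts called at day 6, 130 of the 169 falls and 50 of the 81 rises were called again at day 13, and 1 of the rises was called there in the opposite direction. 119 transcripts were lower and 49 higher on all 3 days after zfp1 RNAi, and 120 and 69 after p53 RNAi.

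Transcripts higher after zfp1 RNAi at day 9 were also mostly called after p53 RNAi at day 13. 339 of 415 were called higher there, against 37.2 for independent lists, with a median log2 fold change of 1.06. In the other direction, 339 of the 1720 transcripts higher after p53 RNAi at day 13 were called higher after zfp1 RNAi at day 9, with a median of 0.28, and 511 when adjusted over the list alone.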
